A study of Rattus norvegicus with 24 samples.

How the data were processed

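RNA from the myocardium of Sprague-Dawley rats was sequenced in 24 libraries. Per the labels' protocols, mitral regurgitation (MR) was made by perforating a mitral leaflet, Sham rats had the operation without that step, the tissue was snap-frozen, RNA was extracted with miRNeasy columns, and sequencing used an Illumina instrument. The groups were Sham at 2 weeks (n = 5) and MR at 2 weeks (n = 4), 10 weeks (n = 5), 20 weeks (n = 5) and 40 weeks (n = 5), taken from the labels. Replicates are numbered within each group. The labels give no batch, sex, age or heart chamber, and do not say that each library came from a separate animal. A p-value therefore measures the spread between these libraries.

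Per the submitters' processing notes, Partek was used with the rat genome build rn6. The aligner, the gene annotation, the counting rule, the strand setting and the way the values were scaled are not given in the sources used here. The deposited files are 4 tables, each holding 1 MR time beside the same 5 Sham libraries, in unit signal: linear normalised gene counts that are never negative. Chromosome, start and end are printed as the tables give them, on rn6, and whether starts count from 0 or 1 is not stated. Locations from the reference gene table (assembly GRCr8) were not used; its symbols matched 10699 of the 10797 symbols found in any table.

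The deposited signal values proved to be gene counts divided by a single factor per library. Between 97.3% and 97.7% of the values in a table were within 0.1 read of a whole read after that factor was undone, and reads recovered in this way gave 7.69 to 12.1 M reads on listed genes per library. The same Sham library differed between tables by a constant (ratios 0.916 to 1.00), so its values differ a little between comparisons. The tables list 10433, 10404, 10275 and 10439 genes at 2, 10, 20 and 40 weeks, of which 10129 are in every table. Every listed gene has at least 1 read in every library of its table, so a gene absent from a single library is not listed and a gene switched on or off cannot be seen. The least read gene of a table reached 31 or 32 reads in its highest library, and no gene of the mitochondrial chromosome is listed, so genes under such a level cannot be seen here. Intervals and floors that depend on depth would cover counting error only, and the spread between libraries was larger: in 46 pairs of libraries of the same group, the chi-square per gene was 10.5 to 112, where counting error alone gives about 1.

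Each MR time was compared with Sham in its own table. Values were tested as log2(value + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation along a mean trend. Genes needed a mean of at least 1 over the table, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05. A log2 fold change is on that log2(value + 1) scale, which understates the change of genes with low values. Tests are two-sided. MR times were compared with each other in a single fit of all 24 libraries and 9988 genes, after each library had been rescaled by the median of its ratios to the gene-wise geometric mean. Raw counts would have been tested with edgeR by the design; since the tables hold scaled counts, limma was the test used, and edgeR 4.0.16 and DESeq2 1.42.0 were run on the recovered reads as alternatives chosen after seeing the data. They called 0 and 57 genes at 2 weeks, 5 and 83 at 10 weeks, 8 and 92 at 20 weeks, and 4602 and 4828 at 40 weeks.

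Gene lists, 41 in number, were tested with camera at a preset inter-gene correlation of 0.01 and again with an estimated correlation, when at least 5 members were measured. That left 37 lists at 2 weeks and 38 at the other times. Not tested were the mitochondrial DNA-encoded genes (0 of 15 measured), neutrophil markers (3 of 14), sex-linked genes (2 of 7) and, at 2 weeks, skeletal muscle markers (4 of 15). A list score per library, the mean log2 value of the members less the median over all tested genes, was compared by an exact permutation test. It was chosen after seeing the data, and the smallest p it can give is 0.00794. With 37 or 38 lists adjusted together, a fully separated list cannot pass unless several others also reach the smallest p. A miss of the adjusted threshold is therefore weak evidence against a list. The tests, the lists, the alternatives not marked as added and the rule for named genes were set before the data were examined. That rule names, per comparison with Sham, the 5 largest rises and 5 largest falls among genes that passed, whose groups do not overlap and whose mean is at or above the median of tested genes, leaving out locus identifiers. It also names a panel of 12 genes (Nppa, Nppb, Myh6, Myh7, Acta1, Atp2a2, Col1a1, Col3a1, Postn, Timp1, Cpt1b and Des), up to 4 members with the smallest p from up to 6 lists that passed camera, and the 3 largest rises and falls between MR times within the same limits on overlap and mean. Overlap of calls between times was set beside a simulation of unchanged groups (100 draws) and beside Sham libraries split into groups of 2 and 3. Each draw added deviations of libraries from their own group means, taken from all 24 libraries, to the Sham gene means. It compared 2 such groups of 5 with a shared control group of 5, so the real Sham group was not reused.

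The tests were tried on simulated data in which known genes were changed. With the library numbers of the 2-week comparison, 37 of 99 genes with a 2-fold change and 91 of 96 with a 4-fold change were recovered, with 14 false calls among 10151 genes. At 10 weeks, 64 of 98 and 98 of 99 were recovered with 4 false calls among 10079 genes. The 20-week figures were 71 of 98 and 98 of 98 with 6 false calls among 10003 genes, and the 40-week ones 68 of 98 and 94 of 94 with 5 false calls among 10071. Simulated genes were independent, so this does not test lists whose members move together. Alternatives set in advance were pseudocounts of 0.1 and 5, no filter, a mean of at least 10, median-ratio rescaling, quantile normalization and library weights. They also included empirical Bayes without a trend or robust, a fit of all libraries, stricter thresholds, title numbers as a block, and each library left out in turn. Added after seeing the data were the count tests, the list score test, a fit without 3 outlying libraries, and removal of each library's trend with gene span. Tables were read with pandas 2.3.3 and numpy 2.4.6 in Python 3.11.15 and plots drawn with matplotlib 3.10.9. Every sample column was used.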

Results

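Myocardial RNA was measured in rats with a surgically made leak of the mitral valve (MR) and in rats with a sham operation. A leaking mitral valve returns part of each beat to the atrium and loads the heart with extra volume. There were 5 Sham libraries, taken 2 weeks after surgery, and 4, 5, 5 and 5 MR libraries taken at 2, 10, 20 and 40 weeks. All Sham libraries are from 2 weeks, so each comparison at 10, 20 or 40 weeks holds the time with MR, the age of the rats and any difference in handling together. Sham libraries held 8.95 ± 0.774 M reads on listed genes (SD, n = 5). MR libraries held 9.27 ± 1.16 M at 2 weeks (SD, n = 4), and 10.5 ± 1.34, 9.48 ± 0.483 and 9.71 ± 1.07 M at 10, 20 and 40 weeks (SD, n = 5 each). Levels are normalised read counts, given for MR against Sham as mean ± SD, and fold changes are log2 values with their SE.

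Over the genes shared by all tables, the first principal component held 48.7% of the variance and the second 11.8%. MR at 40 weeks scored 46.0 ± 11.6 on the first (SD, n = 5, range 28.3 to 57.2). Every other library lay at or below 21.7, the score of an MR library at 20 weeks. Sham scored −9.60 ± 16.3 (SD, n = 5), and MR at 2, 10 and 20 weeks −12.8 ± 20.8 (SD, n = 4), −22.9 ± 4.83 and −3.23 ± 17.7 (SD, n = 5 each), so these groups overlapped on the first component. On the second, MR at 2 weeks (−28.8 to −9.57) lay below MR at 10 weeks (−6.93 to 13.4) and 20 weeks (8.75 to 25.4). Sham libraries (−21.7 to 13.4) overlapped each of these groups there.

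**Figure D1:**
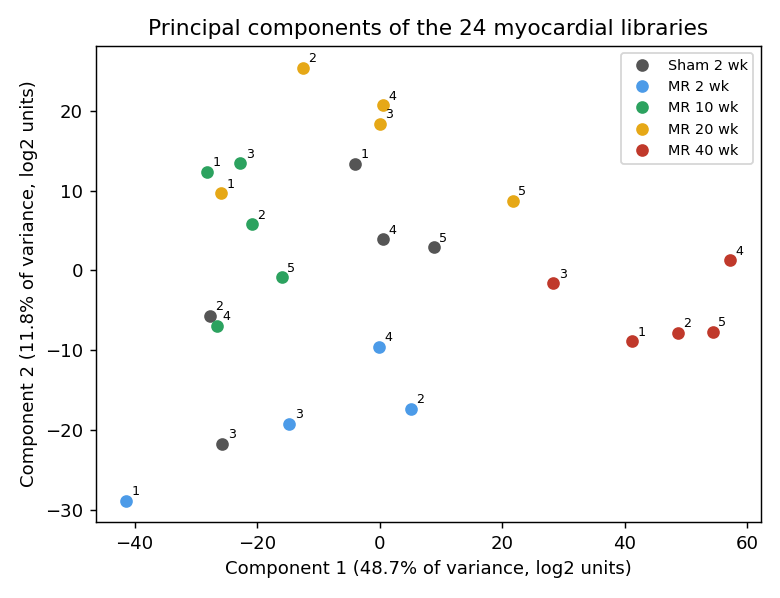
Scores of the 24 libraries on the first principal component (horizontal axis, 48.7% of the variance) and the second (vertical axis, 11.8%), with a colour per group and the replicate number beside each point. MR at 40 weeks lies between 28.3 and 57.2 on the horizontal axis and every other library at or below 21.7.

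MR at 2 weeks was compared with the Sham group of the same time to see what differs early after the leak begins. Genes of dividing cells stood higher in MR. Of the 40 measured cell cycle genes 37 had a positive fold change, the median was 0.85, and the list score of 4 of 4 MR libraries lay above that of every Sham library (adjusted exact permutation p = 0.294). Top2a, which untangles DNA in dividing cells, was at 8.05 ± 2.87 against 2.43 ± 0.906 (SD, n = 4 and 5), a difference of 1.39 ± 0.27 SE. Cenpf, a kinetochore protein, differed by 1.52 ± 0.27 SE, the spindle factor Tpx2 by 1.40 ± 0.27 SE, and Kif20a, a kinesin of cytokinesis, by 1.26 ± 0.22 SE. The groups did not overlap for any of these 4 genes, yet each had an adjusted p of 0.313. Over all genes 0 cell cycle genes passed, and 26 passed adjusted over the list alone. Camera gave the list an adjusted p of 6.71e-42, and adjusted p = 0.316 with an estimated correlation. In the comparisons at 10, 20 and 40 weeks, which share the Sham libraries, 33, 32 and 33 cell cycle genes were measured. A gene is listed by its reads, so some of the 40 may be measured only because MR at 2 weeks was high. The counts, score and tests of this list at 2 weeks include such genes.

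Macrophage, matrix and mast cell genes also stood higher at 2 weeks. In the macrophage and monocyte list 23 of 28 genes were above 0 (median 0.30, camera adjusted p = 5.56e-08), and adjusted p = 0.527 with an estimated correlation. The mannose receptor gene Mrc1 was at 17.5 ± 3.47 against 9.03 ± 2.60, a difference of 0.90, and Lyve1 differed by 0.83. Extracellular matrix genes were above 0 in 33 of 45 cases (median 0.25, adjusted p = 1.55e-05), and adjusted p = 0.643 with an estimated correlation. The fibronectin gene Fn1 differed by 1.01 and tenascin C (Tnc) by 1.15. Without Sham replicate 3, which stood apart for matrix genes, Fn1 differed by 1.52 (adjusted p = 0.247), and without MR replicate 3 Tnc differed by 0.62 (0.950). The 6 mast cell markers had a median of 0.69 (adjusted p = 5.03e-05; adjusted p = 0.316 with an estimated correlation), with the chymase gene Cma1 at 0.91.

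Genes of energy metabolism stood lower at 2 weeks. Of 72 oxidative phosphorylation genes 1 was above 0 (median −0.35, adjusted p = 2.14e-17), and adjusted p = 0.46 with an estimated correlation. The complex I gene Ndufv1 differed by −0.51 and Atp5g3, of the ATP synthase ring, by −0.51. Fatty acid oxidation (3 of 37 above 0, median −0.41, adjusted p = 4.04e-05) and the tricarboxylic acid cycle (1 of 24 above 0, median −0.38, adjusted p = 1.74e-04) were also lower, each with adjusted p = 0.643 with an estimated correlation. MR replicate 1 carried part of this: without it the tricarboxylic acid cycle list did not pass (0.418). For that list and fatty acid oxidation 1 of 4 MR libraries lay below every Sham library, and 2 of 4 for oxidative phosphorylation (adjusted exact permutation p = 0.711, 0.587 and 0.294). Other lists past camera were cytoskeleton, interferon response, adrenergic signalling, complement, TGF-beta signalling and matrix proteases, which were higher, and proteolysis, atrial markers, sarcomere and lymphocyte markers, which were lower. Their adjusted p ran from 2.04e-04 to 0.0437, and from 0.316 to 0.643 with an estimated correlation. The interferon, complement, TGF-beta, matrix protease, atrial, sarcomere and lymphocyte calls were each lost without at least 1 library (0.0511 to 0.763). The matrix protease list had a median of −0.0034 and a mean of 0.0970. Camera sets a list against all genes, whose median at 2 weeks was −0.0658, so the list was higher by the test. Counts of genes above 0 at 2 weeks hold that offset too.

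Panel genes at 2 weeks did not pass. Myh7, the slow myosin heavy chain, was at 5471 ± 2066 against 9615 ± 3935 (−0.80, adjusted p = 0.840). Timp1, an inhibitor of matrix proteases, was at 15.3 ± 7.68 against 7.25 ± 4.82 (adjusted p = 0.821), and the natriuretic peptide gene Nppa differed by −0.41, adjusted p = 0.937. The size and sign of the Nppa value rest on single libraries: it was −1.38 without MR replicate 4 (0.729), 0.30 without MR replicate 3 (0.978), −0.06 without Sham replicate 4 (0.998), −0.13 without MR replicate 2 (0.985) and −0.70 without Sham replicate 3 (0.783). limma called 0 of 10173 genes, with 556 at an unadjusted p under 0.05 where chance gives 509. Groups did not overlap for 220 genes (2.16%, against 1.59% by chance). edgeR on the recovered reads called 0 as well. DESeq2 called 57 genes (47 higher), library weights 22 and a fit of all libraries 27, and Top2a, Cenpf, Tpx2 and Kif20a passed in each of these 3.

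MR at 10 weeks was compared with Sham to follow the response into the chronic phase. The largest rises by the rule for named genes began with Sult1a1, a sulfotransferase, at 39.5 ± 15 against 11.9 ± 3.69 (SD, n = 5 and 5), a rise of 1.62 ± 0.24 SE. Per2, a repressor of the circadian clock, was at 123 ± 26.1 against 47.2 ± 15.2 (1.39 ± 0.20 SE), and Fmo2, a flavin monooxygenase, at 40.8 ± 9.62 against 16.5 ± 3.49 (1.24 ± 0.18 SE). All 3 had an adjusted p of 0.0192. Tcap, the titin cap of the sarcomere's Z-disc, rose by 1.03 ± 0.18 SE and the splicing kinase gene Clk1 by 1.02 ± 0.17 SE (both adjusted p = 0.0358). On rn6 these lie at chromosome 1, 198100586 to 198104107 (Sult1a1), chromosome 9, 98555156 to 98597324 (Per2), chromosome 13, 80755051 to 80775265 (Fmo2), chromosome 10, 86337703 to 86338862 (Tcap) and chromosome 9, 65296777 to 65307996 (Clk1). In all, 16 genes rose and 1 fell of 10096, and MR and Sham libraries did not overlap for any of them. The fall, named after its values were seen, was RT1-CE11, at 0.337 ± 0.143 against 2.57 ± 1.43 (−1.34, adjusted p = 0.0358). It belongs to the major histocompatibility complex, whose near-identical genes can share reads, so it is uncertain. By direction DESeq2 called 57 rises and 26 falls, edgeR 4 and 1, and library weights 25 and 2. The median fold change of all genes was 0.06 on the deposited scale and −0.01 after median-ratio rescaling, which left 5 rises and 0 falls. Of 1212 genes at an unadjusted p under 0.05 on the deposited scale, 959 were higher. The excess of rises may partly follow that offset of all genes.

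Among gene groups at 10 weeks, 5 of 6 adipocyte markers rose adjusted over the list alone and 0 over all genes (median 0.61, camera adjusted p = 0.00252), and adjusted p = 0.254 with an estimated correlation. The adipocyte score was higher in 5 of 5 MR libraries than in any Sham library (adjusted exact permutation p = 0.302). The lipase gene Lipe was at 0.83, adjusted p = 0.0896, and complement factor D (Cfd) at 0.94, adjusted p = 0.0918. Macrophage markers were above 0 in 24 of 27 cases (median 0.32, adjusted p = 7.70e-04), and 3 rose adjusted over the list alone. Fibroblast markers were higher too (median 0.26, adjusted p = 0.0133), both lists having adjusted p = 0.921 with an estimated correlation. The fibroblast call was lost without Sham replicate 2 or 5 or MR replicate 4 or 5 (0.0707 to 0.297). Mrc1 was at 0.87, adjusted p = 0.0682, and the complement gene C1qc at 0.62. Cell cycle genes lay below Sham at this time (6 of 33 above 0, median −0.32, adjusted p = 1.89e-08), and adjusted p = 0.631 with an estimated correlation, Top2a being at −0.82 and Mki67 at −0.85.

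Oxidative phosphorylation (median −0.09, adjusted p = 6.83e-07), immediate early genes (−0.25, 3.03e-05), the tricarboxylic acid cycle (−0.14, 6.92e-04), extracellular matrix (−0.10, 0.00394) and cytoskeleton (−0.05, 0.0251) were lower by camera at 10 weeks. Cardiac stress genes were higher (14 of 14 above 0, 0.29, 0.0386), and all 6 lists had adjusted p = 0.921 with an estimated correlation. The matrix call was lost without Sham replicate 3 (0.684), MR replicate 1 (0.0514) or 2 (0.138), and that of the tricarboxylic acid cycle without Sham replicate 1 (0.0890) or MR replicate 4 (0.0793). Cardiac stress did not pass without Sham replicate 2, 3 or 5 or MR replicate 3 or 4 (0.0520 to 0.376), nor cytoskeleton without Sham replicate 2 or 3 or MR replicate 3 or 5 (0.0553 to 0.115). Of 15 circadian clock genes 2 rose, Per2 and Tef, and 3 adjusted over the list alone, while the list did not pass (adjusted p = 0.126). Tef, named after its values were seen, rose by 0.86, adjusted p = 0.0491. Nppa was at 1332 ± 1721 against 245 ± 173 (1.71, adjusted p = 0.361), Myh7 at 0.50, Myh6 at −0.50 and Col1a1 at −1.08 (adjusted p = 0.283). Single libraries moved these values: Col1a1 was at −0.66 without Sham replicate 3 (0.233), Myh7 at 0.29 without Sham replicate 1 (0.723), and Nppa at 1.04 and Myh6 at −0.22 (0.791) without MR replicate 4. At an unadjusted p under 0.05 there were 1212 genes, and groups did not overlap for 247 (2.45%, against 0.794% by chance). The calls rest on few libraries: 0 genes passed without any of Sham replicates 4 and 5 or MR replicates 1, 2 and 3. Tcap was lost also without Sham replicate 2 or 3 or MR replicate 4 (0.0535, 0.0590 and 0.0680), and Clk1 without MR replicate 4 (0.0796). Median-ratio rescaling left 5, without Tcap (0.0787) and Clk1 (0.0756).

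MR at 20 weeks gave 7 genes that rose and 0 that fell of 10025. The balance of directions depended on the fit. DESeq2 gave 44 rises and 48 falls and library weights 18 and 12, while edgeR gave 8 and 0 and median-ratio rescaling 9 and 0. Largest by the rule was Ankrd23, a stretch-responsive ankyrin repeat protein of muscle, at 42.4 ± 16.7 against 14.3 ± 3.01 (SD, n = 5 and 5), a rise of 1.44 ± 0.24 SE, adjusted p = 0.0427. Sult1a1 rose again (31.2 ± 7.75 against 11.5 ± 3.56, 1.37 ± 0.21 SE, adjusted p = 0.0379), as did Card9, an adaptor of innate immune signalling (29.6 ± 6.81 against 12 ± 2.39, 1.22 ± 0.17 SE, adjusted p = 0.0194). Ucp3, a mitochondrial carrier linked to fat burning, rose by 1.44 ± 0.24 SE, adjusted p = 0.0427, and its groups overlapped. The Ankrd23 call was lost without any library but MR replicate 1 (0.0566 to 0.131), and that of Sult1a1 without Sham replicates 3 to 5 or MR replicates 1 to 4 (0.0555 to 0.124). Card9 was lost without Sham replicate 4 or 5 or MR replicate 2, 3 or 4 (0.0520 to 0.0910), and Ucp3 without Sham replicate 1, 3, 4 or 5 or MR replicate 1, 2 or 3 (0.0566 to 0.164). The others, named after their values were seen, were Dusp15 (2.01), Dupd1 (1.38) and Ccdc181 (1.26). Ankrd23 lies at chromosome 9, 43110986 to 43117586, Card9 at chromosome 3, 3798346 to 3806714 and Ucp3 at chromosome 1, 165482912 to 165495897.

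Genes of fuel use and cardiac stress were higher at 20 weeks. Of 37 fatty acid oxidation genes 35 were above 0 and 1, Ucp3, rose (median 0.27, camera adjusted p = 5.60e-10), and adjusted p = 0.373 with an estimated correlation. Pdk4, which shuts pyruvate out of the mitochondrial cycle, was at 1.24. Of 14 cardiac stress genes 1 rose over all genes and 8 adjusted over the list alone (median 0.65, adjusted p = 1.99e-08), and adjusted p = 0.27 with an estimated correlation. The stretch-sensitive gene Ankrd1 was at 5082 ± 979 against 2811 ± 709 (0.87, adjusted p = 0.160) and Gdf15 at 1.02. The tricarboxylic acid cycle (24 of 24 above 0, 3.97e-05), heat shock proteins (6.22e-05), glycolysis (0.00344), sarcomere (0.00546), proteolysis (0.00546), adipocyte markers (0.00655) and ion channels (0.0160) were also higher. Their adjusted p ran from 0.245 to 0.557 with an estimated correlation. Without Sham replicate 3 the sarcomere (0.0503), proteolysis (0.0502), glycolysis (0.0572) and ion channel (0.0586) calls were lost. Glycolysis was lost also without Sham replicate 2 or MR replicate 5 (0.0612 and 0.0678), and ion channels without Sham replicate 2 or MR replicate 4 or 5 (0.0695, 0.0980 and 0.110).

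Interferon, proliferation and immediate early genes were lower at 20 weeks. Of 32 interferon response genes 0 were above 0 and 7 fell adjusted over the list alone, against 0 over all genes (median −0.39, adjusted p = 2.81e-13; adjusted p = 0.245 with an estimated correlation). The antiviral genes Oasl and Mx2 were at −0.72, adjusted p = 0.108, and −0.80. In the cell cycle list 6 of 32 fell adjusted over the list alone (median −0.35, adjusted p = 1.76e-10), with the cyclin gene Ccnd1 at −0.87, adjusted p = 0.0986. Among immediate early genes 14 of 27 fell and 1 rose adjusted over the list alone (median −0.50, adjusted p = 1.99e-10), with Nr4a1 at −1.25. Over all genes 0 members of either list passed, and both had adjusted p = 0.245 with an estimated correlation.

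Matrix, vessel and immune genes were lower at 20 weeks too. In the extracellular matrix list 11 of 43 genes fell adjusted over the list alone and 0 over all genes (median −0.28, adjusted p = 7.80e-10), and adjusted p = 0.329 with an estimated correlation. The fibrillar collagen genes Col1a1 (68.1 ± 12.5 against 232 ± 209) and Col3a1 (224 ± 40.2 against 576 ± 337) differed by −1.45, adjusted p = 0.197, and −1.23, adjusted p = 0.108. Col15a1, of the basement membrane zone, was at 70.4 ± 11.9 against 113 ± 11 (−0.69, adjusted p = 0.0986). On the joined scale Sham replicate 3 stood apart for collagens, at 639 for Col1a1 against 110 to 151 in the other Sham libraries. Without it Col1a1 and Col3a1 passed (0.0447 and 0.0472). Endothelial markers were above 0 in 1 of 25 cases (median −0.31, adjusted p = 9.66e-06; adjusted p = 0.245 with an estimated correlation), and the score of 5 of 5 MR libraries lay below every Sham library (adjusted exact permutation p = 0.121). Macrophage markers (0.00243), lymphocyte markers (0.00344), matrix proteases (0.00543), TGF-beta signalling (0.00655), cytoskeleton (0.0190) and ribosomal proteins (0.0278) were lower, with adjusted p from 0.245 to 0.739 with an estimated correlation. Without Sham replicate 3 the ribosomal (0.940), macrophage (0.192) and matrix protease (0.0754) calls were lost. The macrophage call was lost also without MR replicate 4 (0.0753), the cytoskeleton call without Sham replicate 4 or MR replicate 1 (0.0795 and 0.0869), and the ribosomal call without Sham replicate 2 or MR replicate 1, 4 or 5 (0.106 to 0.459). At an unadjusted p under 0.05 there were 951 genes, and groups did not overlap for 180 (1.80%, against 0.794% by chance). The 7 calls became 2 without Sham replicate 4 or 5, 3 without MR replicate 2, 3 or 4, and 14 without MR replicate 5.

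**Figure D2:**
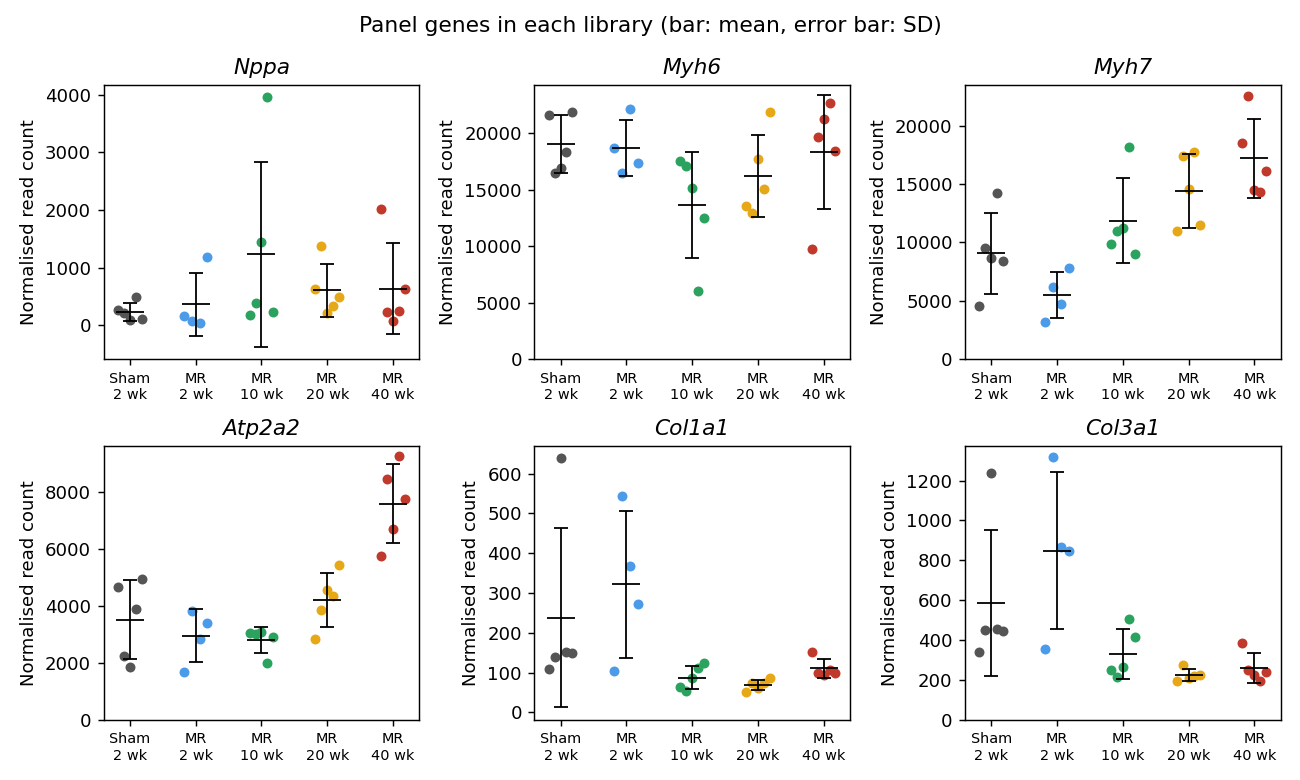
Normalised read count of Nppa, Myh6, Myh7, Atp2a2, Col1a1 and Col3a1 in each library (points) by group, on the joined median-ratio scale, with bars at the group mean and error bars of 1 SD. Atp2a2 reaches 5778 to 9264 in MR at 40 weeks against 1873 to 4936 in Sham, while Nppa runs from 83.6 to 2013 inside MR at 40 weeks.

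MR at 40 weeks, the longest time with a leak, differed from Sham far more widely. Maoa, a monoamine oxidase that breaks down catecholamines and serotonin, rose furthest (255 ± 169.9 against 26.5 ± 13.1, 3.13 ± 0.43 SE, n = 5 each). Ccnd2, a D-type cyclin (36 ± 12.7 against 3.71 ± 2.39, 3.02 ± 0.35 SE), and Cavin4, a muscle protein of caveolae (47.1 ± 11.8 against 6.23 ± 4.62, 2.96 ± 0.37 SE), followed. The pacemaker channel gene Hcn4 (30.4 ± 23.1 against 2.91 ± 2.71, 2.93 ± 0.55 SE) and Pkia, an inhibitor of protein kinase A (101 ± 33.4 against 15 ± 10.9, 2.92 ± 0.42 SE), rose as much. Adjusted p of these rises ran from 1.30e-04 to 9.66e-04. The largest falls by the rule for named genes were RT1-CE14 (−1.91 ± 0.22 SE), B4galnt1, which makes complex gangliosides (−1.64 ± 0.21 SE), the ribosomal protein gene Rps28 (−1.64 ± 0.25 SE), Atp5i, of the ATP synthase (−1.62 ± 0.22 SE), and Ndufa1, of complex I (−1.61 ± 0.28 SE). For all 10 genes the MR and Sham libraries did not overlap. Maoa lies at chromosome X, 6554698 to 6620723, Ccnd2 at chromosome 4, 159674885 to 159697208, Cavin4 at chromosome 5, 64413005 to 64420850 and Hcn4 at chromosome 8, 63599907 to 63637325. Pkia lies at chromosome 2, 96595088 to 96668223, B4galnt1 at chromosome 7, 70452641 to 70459557, Rps28 at chromosome 7, 18682071 to 18683441 and Atp5i at chromosome 14, 2325308 to 2326437. RT1-CE14, of a multigene family, is listed at chromosome 20, 4638865 to 4943289 and Ndufa1 at chromosome X, 123803116 to 124516792, spans long for such genes, so both are uncertain.

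Protein synthesis and respiratory chain genes fell together at 40 weeks. Of 76 cytosolic ribosomal protein genes 71 fell and 0 rose, and 73 fell adjusted over the list alone (median −0.97, camera adjusted p = 3.34e-16; adjusted p = 0.871 with an estimated correlation). Rpl36 was at −1.61 ± 0.20 SE and Rpl32 at −1.26 ± 0.17 SE. Of 72 oxidative phosphorylation genes 59 fell and 1 rose, and 60 fell adjusted over the list alone (median −0.83, adjusted p = 2.11e-12; adjusted p = 0.871 with an estimated correlation). Cox7a2, of complex IV, was at −1.27 and Atp5h at −1.31. Interferon response genes fell in 18 of 33 cases with 0 rises, 18 also adjusted over the list alone (median −0.56, adjusted p = 0.00461; adjusted p = 0.994 with an estimated correlation). Ifi27 was at 79.5 ± 21.2 against 227 ± 49.9 (−1.51 ± 0.20 SE) and Bst2 at −1.05. Cell cycle genes fell in 19 of 33 cases and rose in 1, Ccnd2, and the same held adjusted over the list alone (median −0.49, adjusted p = 0.0336; adjusted p = 0.994 with an estimated correlation). That camera call was lost without Sham replicate 2, 3 or 4 or MR replicate 3 or 4 (0.0518 to 0.122).

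Genes of excitability and adrenergic signalling rose at 40 weeks. Of 31 ion channel and gap junction genes 14 rose and 4 fell, and 16 and 4 did adjusted over the list alone (median 0.45, adjusted p = 1.58e-04; adjusted p = 0.857 with an estimated correlation). Kcnk3, a background potassium channel, was at 74.9 ± 18 against 12 ± 6.57 (2.68 ± 0.31 SE) and the pacemaker channel gene Hcn2 at 113 ± 31.8 against 35 ± 13.1 (1.69 ± 0.27 SE). Kcnj3, of the acetylcholine-gated potassium current, rose by 1.94 ± 0.27 SE. Markers of atrial muscle, a list that holds Kcnj3, rose in 5 of 11 cases and fell in 1 (adjusted p = 0.118). In the adrenergic, renin-angiotensin and natriuretic list 12 of 28 rose and 4 fell, also adjusted over the list alone (median 0.24, adjusted p = 5.04e-04; adjusted p = 0.0971 with an estimated correlation). Corin, the protease that activates natriuretic peptides, was at 38.8 ± 14.7 against 8.97 ± 1.28 (1.93 ± 0.21 SE), and the receptor gene Adra1a rose by 1.82 ± 0.26 SE.

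Calcium handling genes rose in 11 of 27 cases and fell in 3 at 40 weeks (median 0.28, adjusted p = 0.00501), and adjusted p = 0.857 with an estimated correlation. Cardiac stress genes rose in 8 of 14 and fell in 2 (0.74, 0.00369), tricarboxylic acid cycle genes rose in 7 of 24 and fell in 2 (0.43, 0.0177), and fatty acid oxidation genes rose in 10 of 37 and fell in 5 (0.21, 0.0243). These 3 lists had adjusted p from 0.871 to 0.994 with an estimated correlation. The tricarboxylic acid cycle call was lost without Sham replicate 3 or MR replicate 4 (0.0838 and 0.0518), and that of fatty acid oxidation without Sham replicate 3 or 4 or MR replicate 3 or 4 (0.0506 to 0.0915). The exact permutation test of list scores gave an adjusted p of 0.0335 for 9 lists, with 5 of 5 MR libraries beyond every Sham library. Ribosomal proteins and oxidative phosphorylation were lower, and ion channels, adrenergic signalling, calcium handling, cardiac stress, glycolysis, heat shock and hypoxia higher. It missed for interferon response (0.0862), the tricarboxylic acid cycle and fatty acid oxidation (0.113 each) and cell cycle (0.151).

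In the panel, Atp2a2, the calcium pump of the sarcoplasmic reticulum, rose at 40 weeks (6726 ± 1165 against 3607 ± 1537, 1.01 ± 0.31 SE, adjusted p = 0.0169), a call lost without Sham replicate 2 (0.0534). Myh7 rose (15269.9 ± 3029 against 9179.7 ± 3816, 0.81 ± 0.31 SE, adjusted p = 0.0468), a call lost without any of 8 of the 10 libraries, with adjusted p up to 0.130 (without Sham replicate 1). It held without Sham replicate 4 or MR replicate 3. The collagen genes Col3a1 (230.4 ± 71.7 against 578 ± 327, −1.23 ± 0.28 SE, adjusted p = 0.00310) and Col1a1 (98.2 ± 23.7 against 232 ± 205, −0.95 ± 0.35 SE, adjusted p = 0.0368) fell. The Col1a1 call was lost with median-ratio rescaling (0.0935) and without MR replicate 2, 3, 4 or 5 (0.0721, 0.0615, 0.0638 and 0.0817). Sham replicate 3, the high collagen library described for 20 weeks, carries much of its size: without it Col1a1 was at −0.53 (adjusted p = 0.0198). These genes lie at chromosome 12, 39553903 to 39603327 (Atp2a2), chromosome 15, 33634422 to 33656090 (Myh7), chromosome 9, 52023295 to 52059222 (Col3a1) and chromosome 10, 82745801 to 82762791 (Col1a1). Nppa (0.68, adjusted p = 0.423), Nppb (−0.29), Myh6 (−0.29, adjusted p = 0.459), Acta1 (0.28), Postn (−1.48, adjusted p = 0.0803), Timp1 (−0.46) and Cpt1b (0.18) did not pass. Single libraries moved these values too. Without Sham replicate 3 Nppb passed (−0.64, adjusted p = 0.0362), while Postn was at −0.75 (0.149), Timp1 at −0.17 (0.528), Cpt1b at 0.06 (0.759) and Nppa at 0.39 (0.661). That Nppb call comes from dropping the lowest Sham library for Nppb, at 102 on the joined scale against 238 to 377 in the others. Myh6 was at −0.09 without MR replicate 1 (0.833) and Acta1 at 0.05 without MR replicate 2 (0.884), and Nppa lay between 0.05 (without MR replicate 1, 0.948) and 1.19 (without MR replicate 3, 0.125). Des was at 0.33, adjusted p = 0.219, and passed with median-ratio rescaling (0.0397), against 0.19 (0.447) without Sham replicate 3.

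Of 10094 genes 4772 passed at 40 weeks (47.3%): 1648 rose and 3124 fell, so 34.5% of the calls were rises. The median fold change of all genes was −0.15 on the deposited scale and −0.01 after median-ratio rescaling, a shift of 0.137. That rescaling gave 2401 rises and 2199 falls (52.2% rises), with 80.6% of the calls kept in direction. The ribosomal, oxidative phosphorylation, ion channel, adrenergic and interferon lists kept their directions under it and under quantile normalization. Groups did not overlap for 2951 genes (29.2%, against 0.794% by chance). Fold changes also went with gene span: the correlation across genes, which are not independent replicates, was 0.300 (Pearson) and 0.326 (Spearman). The median was −0.38 in the shortest quartile of genes and 0.08 in the longest. With each library's span trend removed 62 ribosomal protein genes and 51 oxidative phosphorylation genes fell, and 16 ion channel genes rose.

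**Figure D3:**
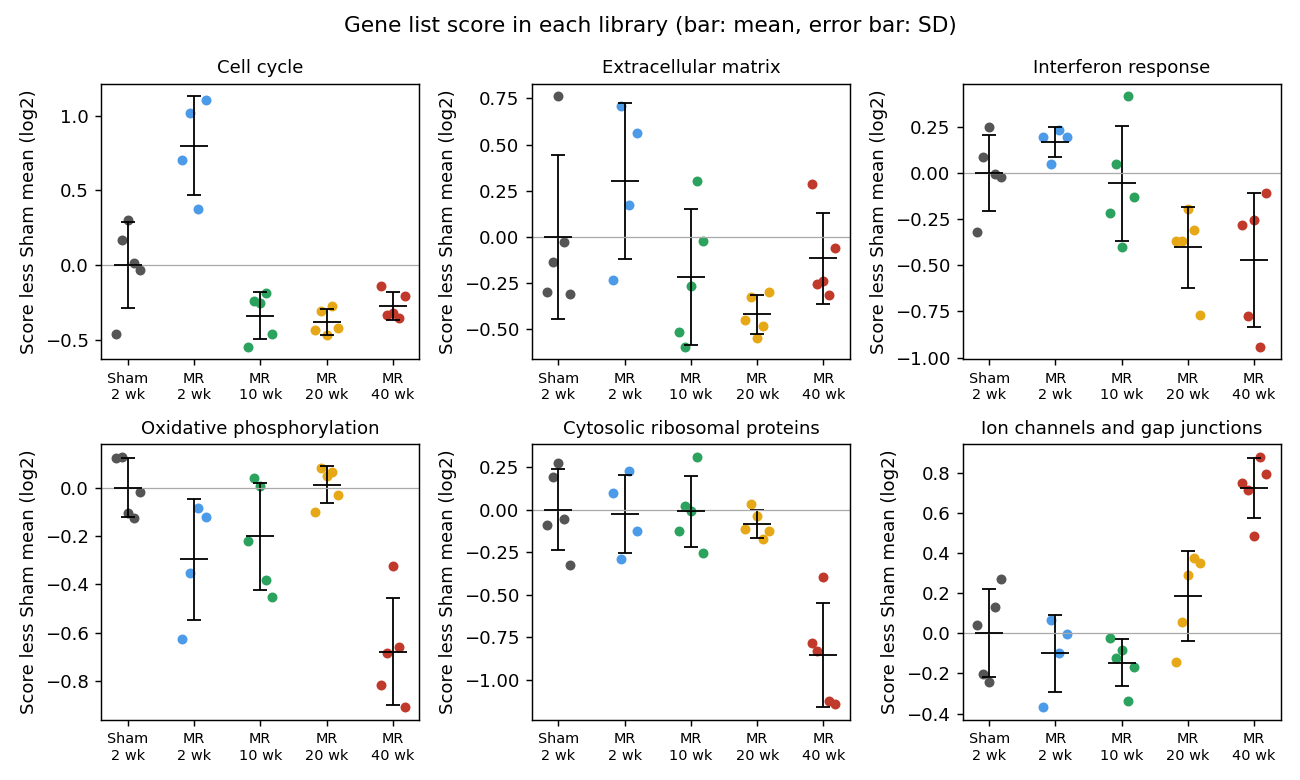
List score of each library (points), as log2 units less the mean of the Sham libraries in the same table, for cell cycle, extracellular matrix, interferon response, oxidative phosphorylation, cytosolic ribosomal protein and ion channel genes, by group, with bars at the group mean and error bars of 1 SD. Cell cycle scores of all 4 MR libraries at 2 weeks lie above every Sham library, and ribosomal and oxidative phosphorylation scores of all 5 at 40 weeks below every Sham library.

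**Figure D4:**
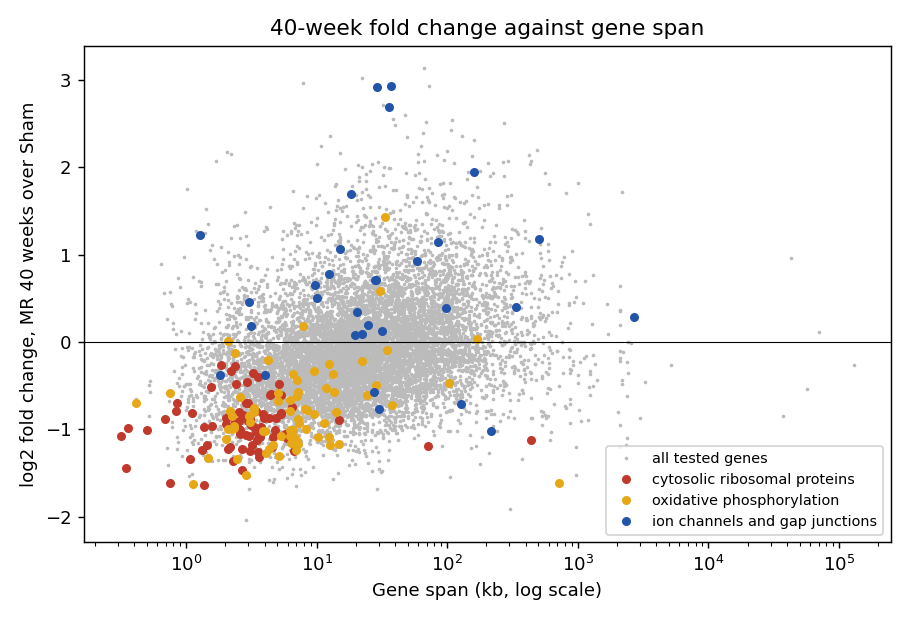
Log2 fold change of MR at 40 weeks against Sham (vertical axis) by gene span in kilobases (horizontal axis, log scale), a point per tested gene, with ribosomal protein, oxidative phosphorylation and ion channel genes coloured. The correlation across genes was 0.326 (Spearman).

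Comparisons between MR times ask how the tissue differs along the course of the leak, though time and age still move together. At 10 weeks against 2 weeks, Fn1 fell, at 18 ± 4.43 against 66.4 ± 32.3 (SD, n = 5 and 4), a difference of −1.72 ± 0.41 SE, adjusted p = 0.0318. The tubulin gene Tubb6 (−1.35 ± 0.25 SE, adjusted p = 0.00485), Col1a2 (−1.27 ± 0.30 SE, adjusted p = 0.0274) and Col1a1 (−1.70 ± 0.41 SE, adjusted p = 0.0319) fell too. Col1a2 is listed at chromosome 4, 29529854 to 31569153, a span too long for the gene, and is uncertain. The Fn1, Col1a1 and Col1a2 calls were each lost without replicate 2, 3 or 4 of 2 weeks or replicate 1, 2 or 3 of 10 weeks (0.0505 to 0.153). Gsn, the actin-severing gelsolin, rose (1411 ± 225 against 601 ± 160.1, 1.25 ± 0.17 SE, adjusted p = 1.18e-04), and so did the glucocorticoid-induced Tsc22d3 (0.88, adjusted p = 0.0437) and Gstz1 (0.87, adjusted p = 0.0243). Gstz1 was lost without replicate 2 or 4 of 2 weeks (0.0963 and 0.0845), and Tsc22d3 without any of replicates 2 to 4 of 2 weeks or 1, 2, 4 and 5 of 10 weeks (0.0559 to 0.137). Of 35 cell cycle genes 23 fell and 0 were above 0, and 30 fell adjusted over the list alone (median −0.99). Scores of 5 of 5 libraries at 10 weeks lay below all at 2 weeks, and camera gave an adjusted p of 8.05e-43, and adjusted p = 0.00538 with an estimated correlation. In the cytoskeleton list 5 of 42 fell and 9 adjusted over the list alone (median −0.25, adjusted p = 1.25e-07), also with adjusted p = 0.00538 with an estimated correlation. The exact permutation test of both scores gave an adjusted p of 0.151. In the extracellular matrix list 5 of 45 fell and 14 adjusted over the list alone (median −0.38, adjusted p = 4.81e-08; adjusted p = 0.614 with an estimated correlation). In all, 30 genes rose and 108 fell of 9988, edgeR called 142, and 1521 had an unadjusted p under 0.05. With library weights 538 rose and 649 fell. The main count was 52 without MR replicate 2 at 2 weeks and 306 without replicate 1 of that group.

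At 20 weeks against 10 weeks a single gene passed of 9988. Pld4, an endolysosomal nuclease of immune cells at chromosome 6, 137323713 to 137331232, fell and is named after its values were seen. It was at 2.88 ± 0.473 against 6.36 ± 0.952 (SD, n = 5 and 5), a difference of −0.92 ± 0.14 SE, adjusted p = 0.00531, with 5 of 5 libraries at 20 weeks below all at 10 weeks. edgeR called 1 gene as well, and 1516 had an unadjusted p under 0.05. With library weights 761 passed, 399 higher and 362 lower, so the count depends on the fit. Fatty acid oxidation genes were higher (35 of 37 above 0, median 0.43, camera adjusted p = 1.50e-10), as were those of the tricarboxylic acid cycle (24 of 24 above 0, median 0.55, 1.50e-10). Macrophage markers were lower (1 of 27 above 0, median −0.50, 1.22e-09), with 13 falls adjusted over the list alone and 0 over all genes, and so were interferon genes (−0.37, 1.55e-08). Camera passed 19 lists there, and 0 with an estimated correlation, where the lowest adjusted p was 0.334. For these 4 lists the exact permutation test gave an adjusted p of 0.121, 0.121, 0.121 and 0.215.

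Among neighbouring MR times, 40 weeks against 20 weeks had the most calls, 2121 rises and 1753 falls of 9988 (edgeR called 3928). Thbs1, the matricellular thrombospondin 1, rose, at 46.1 ± 6.81 against 6.43 ± 5.22 (SD, n = 5 and 5), a difference of 2.86 ± 0.34 SE, adjusted p = 5.18e-06. Pkia (2.74 ± 0.51 SE), Cavin4 (2.69 ± 0.48 SE) and Atp2a2 (7597 ± 1386 against 4219 ± 953, 0.86 ± 0.26 SE, adjusted p = 0.0127) rose with it. Tcap, which had risen at 10 weeks against Sham, fell (437 ± 120.4 against 1177 ± 124, −1.46 ± 0.23 SE, adjusted p = 4.71e-05), with Iqub (−1.73 ± 0.38 SE) and RT1-CE14 (−1.45 ± 0.25 SE). Ribosomal protein genes fell in 67 of 76 cases (median −0.70, camera adjusted p = 7.04e-22; adjusted p = 0.437 with an estimated correlation). Oxidative phosphorylation genes fell in 56 of 72 with 1 rise (−0.65, 6.99e-20; adjusted p = 0.403 with an estimated correlation). Adrenergic signalling genes rose in 12 of 27 cases and fell in 1 (0.45, 0.00355), ion channels rose in 12 of 30 and fell in 1 (0.43, 0.0138), and calcium handling rose in 12 of 26 and fell in 2 (0.32, 0.0318). TGF-beta signalling rose in 14 of 30 and fell in 2 (0.37, 0.00946), and these 4 lists had adjusted p from 0.403 to 0.675 with an estimated correlation. For these 6 lists the scores of 5 of 5 libraries at 40 weeks lay beyond all at 20 weeks (adjusted exact permutation p = 0.0377). Immediate early genes rose in 15 of 27 cases with 0 falls (0.67, 0.00426; adjusted p = 0.990 with an estimated correlation), and the exact test gave an adjusted p of 0.126. Their camera call was lost without MR replicate 3 at 40 weeks (0.0757).

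At 40 weeks against 2 weeks 2427 genes rose and 2131 fell of 9988 (edgeR called 4543). Maoa (3.44 ± 0.44 SE), Pkia (3.15 ± 0.54 SE) and Nipsnap2 (3.04 ± 0.57 SE) were the largest rises by the rule for named genes, which leaves out genes with overlapping groups or a low mean. Tmsb10, an actin-binding thymosin (−1.87 ± 0.27 SE), Slfn13 (−1.82 ± 0.28 SE) and the protease gene Adamts10 (−1.60 ± 0.26 SE) were the largest falls by that rule. MR replicate 1 at 2 weeks stood far above its group for each of these falls, such as Tmsb10 at 319 against 154 to 169. Their size leans on that library, though each call held without it. In the panel Myh7 (1.71, adjusted p = 1.28e-04), Atp2a2 (1.41, adjusted p = 4.01e-04), Cpt1b (0.65, adjusted p = 2.91e-04) and Des (0.70, adjusted p = 0.00702) rose, Des with 0.0502 without MR replicate 1 at 2 weeks. Postn, a marker of activated fibroblasts (−2.32, adjusted p = 0.00879), Col3a1 (−1.60, adjusted p = 6.05e-04), Timp1 (−1.39, adjusted p = 0.00366) and Col1a1 (−1.33, adjusted p = 0.0110) fell, Col1a1 with 0.0545 without MR replicate 2 at 2 weeks. Of 35 cell cycle genes 27 fell and 1 rose (median −1.01, camera adjusted p = 8.45e-13; adjusted p = 0.328 with an estimated correlation). Ribosomal proteins fell in 67 of 76 cases (−0.79, 2.67e-20), macrophage markers in 16 of 27 with 0 rises (−0.69, 7.47e-05), and interferon genes in 19 of 33 with 1 rise (−0.65, 2.22e-05). Oxidative phosphorylation fell in 42 of 72 with 5 rises (−0.44, 2.89e-06). Fatty acid oxidation rose in 25 of 37 cases and fell in 2 (0.71, 2.22e-05) and the tricarboxylic acid cycle rose in 16 of 24 with 0 falls (0.90, 2.22e-05). These 6 lists each had adjusted p = 0.576 with an estimated correlation. Ion channels rose in 18 of 30 and fell in 3 (0.75, 7.96e-05; adjusted p = 0.338 with an estimated correlation). Atrial markers, a list that holds the channel gene Kcnj3, rose with them in 5 of 11 cases with 0 falls (0.51, 0.00983; adjusted p = 0.328 with an estimated correlation). The exact permutation test of the score passed for the cell cycle, macrophage, tricarboxylic acid cycle, ion channel and atrial lists (adjusted p = 0.0274) and the ribosomal, interferon and fatty acid oxidation lists (0.0355), in 5 of 5 libraries each. It missed for oxidative phosphorylation (0.0965).

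Calls against Sham were seldom shared between times. Ccdc181 and Sult1a1 rose at both 10 and 20 weeks, 2 genes where independent lists would share 0.00964. These 2 comparisons share their Sham libraries, so their lists are not independent. With the Sham libraries split between them, which leaves fewer in each, 0 calls were shared in any of 10 splits. At an adjusted p under 0.01 0 were shared. Ccdc181 and Eya2 rose at both 10 and 40 weeks (2 genes, against 2.47 for rises). Ankrd23, Ccdc181 and Dusp15 rose at both 20 and 40 weeks (3 genes, against 0.941). Clk1, Per2 and Tcap, up at 10 weeks, were down at 40 weeks (−1.29, −0.62 and −1.12, with adjusted p 4.44e-04, 0.0137 and 6.67e-04), among 7 genes called in opposite directions at these times. Of the 9911 genes tested at both times 16 rose at 10 weeks and 3124 fell at 40 weeks, so independent lists would also share several opposite calls. Ccdc181, Dusp15 and Eya2 were named after their values were seen. As limma called 0 genes at 2 weeks (556 at an unadjusted p under 0.05; edgeR 0, DESeq2 57), no call could be shared with that time.

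Since the 4 comparisons share the Sham libraries, pairs of unchanged groups were simulated against a shared control, with 5 libraries in every group. All were built from the Sham gene means and deviations drawn from all 24 libraries. The real Sham group was therefore not reused, nor was the smaller MR group of 2 weeks. The draws gave 0 shared calls. With a mean of 1.38 calls in a comparison, that was nearly fixed in advance and sets no baseline for shared calls. Fold changes in the draws had a mean correlation across genes of 0.501 (−0.117 to 0.835) and a mean covariance of 0.0199. The observed correlations across genes were 0.187 (2 and 10 weeks), −0.194 (2 and 20), 0.0608 (2 and 40), 0.382 (10 and 20), −0.318 (10 and 40) and 0.354 (20 and 40). In that order the observed covariances were 0.0113, −0.0118, 0.00853, 0.0240, −0.0456 and 0.0520. Less the simulated covariance they were −0.00861, −0.0317, −0.0114, 0.00406, −0.0655 and 0.0321. With the Sham libraries split between the members of a pair, the mean correlations were −0.112, −0.352, −0.0197, 0.0797, −0.339 and 0.173.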

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

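Rescaling by median ratios was set in advance, but its use to weigh the 40-week pattern, the tests of the cell cycle pattern, the removal of the gene span trend, and the count tests were chosen only after the results they bear on were seen.

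Almost as many genes passed as did not in MR at 40 weeks, 4772 of 10094, with ribosomal protein and respiratory chain genes down and channel genes up. The tables argue against the authors' scaling as the whole cause, since 80.6% of the calls kept their direction and passed after median-ratio rescaling. They argue against a trend with gene span as the whole cause, since 75.8% did once each library's span trend was removed. Span is the distance from start to end in the genome. Transcript length was not measured, so a bias with transcript length was not tested. An axis of variation that libraries inside the other groups share may carry part of the 40-week pattern. The correlation across genes of the 40-week fold changes with that axis was 0.643 in size, and 41.1% of the change lay along it. Those libraries ranged from −41.1 to 25 on the axis against a shift of 37.5 for MR at 40 weeks, with ribosomal protein genes low on it (median percentile 24.9) and ion channel (85.6) and tricarboxylic acid cycle genes (96.1) high, but oxidative phosphorylation genes near its middle (56.5), so it leaves their fall unexplained. Long MR, the age of the rats and a difference in handling at that time stay open and untested, since no Sham library is older than 2 weeks.

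Cell cycle genes stood higher in MR at 2 weeks and fell by 10 weeks. Some of the 40 genes scored at 2 weeks may be measured only because MR was high there. The tables argue against a single outlying library as the whole cause of the rise. With any of the 9 libraries left out, the difference in score was 0.685 (without Sham replicate 1) to 0.940, against 0.800 with all. The intervals (lowest end 0.0727) add nothing to this. As every MR score lay above every Sham score, they had to lie above 0 whichever library was left out. Macrophages in the sample may bring the genes of dividing cells with them, and at 2 weeks this cannot be told apart with 4 and 5 libraries: the cell cycle score rose above the macrophage score by 0.421 in MR against Sham, with a wide interval of −0.214 to 1.05 (exact permutation p = 0.127). For the fall the tables argue against fewer macrophages as the whole cause, since the cell cycle score differed by −1.07 from 2 to 10 weeks and the macrophage score by −0.157, a gap of −0.913 with an interval of −1.33 to −0.423 (exact permutation p = 0.00794, the smallest it can give). Proliferation of the heart's own cells after surgery on the valve, or of macrophages that later stop dividing, stays open as a hypothesis, as no cell type was measured on its own. For the fall, the age of the rats and any difference in handling stay open too, since they move with time. Cell cycle genes also lay below the 2-week Sham libraries at the later times, so the fall need not be the end of a response to MR.

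A library at 10 weeks, MR replicate 4, had the lowest Myh6 of its group at 6021 and the highest Nppa at 3954, of which atrial tissue might bring the Nppa. Its score on the atrial marker list, which leaves out Nppa, lay 0.448 SD from the mean of the other 4 libraries, which argues against that source. The same library had the highest Myh7 (18173 against 9003 to 11243), the lowest Atp2a2 (2001 against 2919 to 3081) and the highest Postn (17 against 1.55 to 5.01), each far from the rest of its group. A more severe leak in that animal stays open and untested, since no measure of the heart's function is given.

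Sham replicate 3 stood far above the other Sham libraries for Col1a1 (639 against 110 to 151), Col3a1 (1239 against 340 to 453), Postn (82.7 against 2.11 to 11.4) and Timp1 (16.3 against 3.88 to 6.33). MR replicate 1 at 40 weeks did so for Nppa (2013 against 83.6 to 624), Col1a1 (152 against 93.8 to 107) and Col3a1 (388 against 195 to 248), and MR replicate 4 at 2 weeks for Nppa (1178 against 36.9 to 161). MR replicate 1 at 2 weeks was highest in Tmsb10 (319 against 154 to 169), Slfn13 (44.8 against 17.4 to 21.1) and Adamts10 (133 against 55.2 to 63.3). MR replicate 3 at 40 weeks was lowest in Ccnd2 (15 against 45.2 to 49.8), and MR replicate 5 at 20 weeks highest in Thbs1 (15.7 against 3.22 to 5.41). These values are on the joined scale. Panel genes were examined in all groups and the largest rises and falls in the groups of their own comparison, not the other list members. Of these 126 gene and group pairs 16 had such a library. The 6.3 that chance would give assumes normal values and independent genes. These are linear counts, and several genes flagged the same library, so the excess over 6.3 is not a test.

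MR times differed from each other in 138 genes (10 against 2 weeks), 1 gene (20 against 10), 3874 genes (40 against 20) and 4558 genes (40 against 2), each a direct test between the times. In the panel, Col1a1 fell from 2 to 10 weeks (−1.70) and Atp2a2 rose from 20 to 40 weeks (0.86). From 2 to 40 weeks Myh7 (1.71), Atp2a2 (1.41), Des (0.70) and Cpt1b (0.65) rose and Postn (−2.32), Col3a1 (−1.60), Timp1 (−1.39) and Col1a1 (−1.33) fell. By the rule for named genes, which leaves out genes with overlapping groups or a low mean, the largest differences from 2 to 10 weeks were Gsn (1.25), Tsc22d3 (0.88), Gstz1 (0.87), Fn1 (−1.72), Tubb6 (−1.35) and Col1a2 (−1.27). From 20 to 40 weeks they were Thbs1 (2.86), Pkia (2.74), Cavin4 (2.69), Iqub (−1.73), Tcap (−1.46) and RT1-CE14 (−1.45), and from 2 to 40 weeks Maoa (3.44), Pkia (3.15), Nipsnap2 (3.04), Tmsb10 (−1.87), Slfn13 (−1.82) and Adamts10 (−1.60), all log2 differences.

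Other splits of the same libraries into groups of the same sizes were drawn for each count, 100 of 126 possible, the real split included. At 40 weeks against Sham 1 split gave as many genes, the real one (4772, highest other 2358). The same held for 40 against 20 weeks (1 split, 3874, highest other 3291) and 40 against 2 weeks (1 split, 4558, highest other 3921). A share of 1 in 100 is the smallest these draws can give, and it argues against chance without excluding it. Another split called as many or more at 10 weeks (4 splits, 17 genes, highest other 59) and 20 weeks (2 splits, 7 genes, highest other 62). So it did for 10 against 2 weeks (2 splits, 138, highest other 162) and 20 against 10 weeks (2 splits, 1, highest other 1). The share of splits was under 5 in 100 for each of these counts taken alone. It was not adjusted for the number of counts and does not exclude chance. At 2 weeks the real count is 0, which all 100 splits reach by definition (highest other 1627), so nothing follows about chance there. The median count of the other splits was 0 at 10 and 20 weeks. Why a split there called several times the real count was not tested. For the number of lists past camera, chance cannot be excluded at any time: 21 splits gave as many at 2 weeks (17, highest other 25), 62 at 10 weeks (10, highest other 24), 5 at 20 weeks (20, highest other 21) and 65 at 40 weeks (10, highest other 21).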

How the results depend on the processing

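The count tests, the fits without outlying libraries (Sham replicate 3, MR replicate 1 at 2 weeks, MR replicate 4 at 10 weeks), the span trend, and libraries left out of list tests were chosen only after the results were seen. Where no reason stands beside a value, the cause was not tested.

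Among named genes that passed 0 changed sign, while some that had not passed did so with a library left out, such as Nppa at 2 weeks. Against Sham, 1126 of 1162 gene values at 40 weeks stayed on the same side of the threshold, 840 of 902 at 20 weeks, 995 of 1059 at 10 weeks and 909 of 923 at 2 weeks. Between MR times 256 of 305 (10 against 2 weeks), 215 of 215 (20 against 10), 303 of 305 (40 against 20) and 302 of 305 (40 against 2) did. The 215 are values of the 12 panel genes, none of which passed, so they say nothing about how stable a call is. For lists against Sham, 441 of 518, 524 of 570, 507 of 570 and 533 of 569 values stayed on the same side at 2, 10, 20 and 40 weeks. Between MR times 113 of 168, 197 of 247, 76 of 84 and 158 of 180 list values did. The lists that reversed were sarcomere at 2 weeks with quantile normalization (adjusted p = 0.966), and from 2 to 10 weeks oxidative phosphorylation without MR replicate 1 at 2 weeks (0.898; 1.15e-04 to 0.898 with a library left out) and fibroblast markers with outlying libraries left out (0.862); none passed there.

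The 0 genes of 2 weeks became 22 with library weights, 27 in a fit of all libraries and 57 with DESeq2, and stayed 0 without any single library. The 17 genes of 10 weeks became 5 with median-ratio rescaling, 27 with weights, 9 without a mean trend, 3 in a fit of all libraries, and 0 at an adjusted p under 0.01. It became 5 with edgeR, 83 with DESeq2, 1 with outlying libraries left out (fewer samples) and 9 with the span trend removed. Leaving out a library gave 0 to 29: 0 without Sham 4 or 5 or MR 1, 2 or 3, 7 without MR 4, and 29 without Sham 1 or MR 5. The 7 genes of 20 weeks became 4 with a pseudocount of 5, 12 with quantile normalization, 30 with weights, 4 without a mean trend, 11 in a fit of all libraries, 2 at 0.01 and 92 with DESeq2. With a library left out they became 2 to 14 (2 without Sham 4 or 5, 3 without MR 2, 3 or 4, 14 without MR 5). The 4772 of 40 weeks became 2664 with a mean of at least 10 (fewer genes tested), 3007 at 0.01 and 2977 with a 1.5-fold minimum, and 4035 to 4948 with a library left out. Lists past camera numbered 0 at each of 2, 10, 20 and 40 weeks with an estimated correlation, and 13 to 19, 8 to 13, 14 to 23 and 7 to 12 with a library left out.

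From 2 to 10 weeks the 138 genes became 32 with a mean of at least 10, 45 in a fit of those 2 groups alone (fewer samples), 1187 with weights and 336 without outlying libraries. With a library left out they became 52 to 306: 52, 88 and 85 without MR 2, 3 and 4 of 2 weeks, 63 and 76 without MR 1 and 3 of 10 weeks, and 306 without MR 1 of 2 weeks. From 10 to 20 weeks the 1 gene became 2 with a pseudocount of 5, 0 with a mean of at least 10, 3 in a fit of those 2 groups, 761 with weights and 6 without outlying libraries. With a library left out it became 1 to 4 (2 without MR 5 of 10 weeks, 3 and 4 without MR 1 and 2 of 20 weeks). With a mean of at least 10, 20 to 40 weeks gave 2418 and 2 to 40 weeks 2913, and with a library left out 3096 to 4236 and 3480 to 4618. Shared calls of 10 and 20 weeks were 0 at 0.01 and 0 on average with split Sham libraries, those of 10 and 40 weeks 0 and 0.7, and those of 20 and 40 weeks 14.1 on average with split Sham libraries (0 to 131).

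With title numbers as a replicate block, 0 genes passed at 2 weeks. Same-numbered libraries correlated at −0.115, −0.199, −0.0172 and 0.325, and none correlated best with its own number, so they share only a number. The planned DESeq2 fit of deposited raw counts had none to run on, so DESeq2 was run on the recovered reads. Between 250 and 345 listed genes per table had a mean under 1 and were not tested.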

Other observations

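The exact tests of list scores were chosen only after the results were seen.

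At 40 weeks 1648 of 10094 genes rose and 3124 fell, shares beside which the counts of lists that did not pass camera can be read. Of 45 proteolysis and autophagy genes 10 rose and 17 fell, and of 42 cytoskeleton genes 7 rose and 15 fell. Of 44 extracellular matrix genes 6 rose and 14 fell, and of 24 sarcomere genes 7 rose and 7 fell. Their adjusted p was 0.937, 0.968, 0.937 and 0.656. Of 25 endothelial markers 12 fell and 2 rose (median −0.35, adjusted p = 0.310), and of 27 macrophage markers 11 fell and 1 rose (−0.43, 0.145). Smooth muscle and pericyte markers fell in 7 of 18 cases and rose in 3, and p53, senescence and cell death genes fell in 9 of 25 and rose in 2 (0.416). Glycolysis genes rose in 9 of 32 cases and fell in 5 (0.0725), heat shock proteins rose in 7 of 23 and fell in 3 (0.0623), and hypoxia and angiogenic factors rose in 6 of 20 and fell in 2 (0.0919).

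Red blood cell markers had a median of −1.29 at 40 weeks with 0 of 6 past the test, against −0.71 at 20 weeks, 0.35 at 10 weeks and −0.33 at 2 weeks. Circadian clock genes, of which Per2 and Tef rose at 10 weeks, rose in 3 of 15 cases and fell in 3 at 40 weeks; the time of day of sampling is not given in the sources used here. From 10 to 20 weeks their list was lower (5 of 15 above 0, median −0.28, camera adjusted p = 0.0409; adjusted p = 0.334 with an estimated correlation), with the scores of 5 of 5 libraries below all at 10 weeks and an adjusted exact permutation p of 0.121. That camera call was lost without replicate 2, 4 or 5 of 10 weeks or replicate 1 or 2 of 20 weeks (0.0509 to 0.0990).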
